A study of Homo sapiens with 2 samples.

How the data were processed

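HaCaT cells, an immortalised human keratinocyte line, were either left unirradiated (0 Gy) or given 20 Gy of X-rays at 1.15 Gy per minute. Chromatin was fixed with 1% formaldehyde for 10 minutes, sonicated and immunoprecipitated with an antibody against AIM2, a cytosolic DNA sensor of the inflammasome, per the labels' protocols. Per the same protocols, 10 ng of immunoprecipitated DNA entered each library, which was amplified over 15 cycles and size selected at 250 to 450 bp. There was 1 library per group. The title of the irradiated sample also gives 4 h, and the labels do not state from which event this time counts. The treatment protocol names the irradiation under both samples, so the groups were taken from the treatment characteristic.

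The submitters' processing notes name bcl2fastq 2.20.0.422, Trimmomatic 0.36, BWA 0.7.15-r1140, MACS2 2.1.2 and deepTools 3.2.1, and the build GRCh38.p13. Per the file headers, peaks were called with MACS2 for each library on its own, in paired-end mode, with narrow peaks, a q-value limit of 0.05, an effective genome size of 3088286401 bp, at most 1 fragment kept per position and no control library. The local background was therefore estimated from the immunoprecipitated library itself, over windows of up to 10000 bp. Per the file headers, the minimum peak length was the fragment size, which was 177 bp in the 0 Gy library and 170 bp in the 20 Gy library. An input library was not used here, so regions with more reads for reasons other than the antibody can be called as peaks.

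The deposited signal of each peak is its pileup, the coverage by fragments at the summit, and the authors did not scale it between the libraries as far as the file headers show. The deposited p-values and q-values are given as −log10 values against the local background of the same library, per the file headers. The deposited fold enrichment is the ratio of pileup to that background, per the file headers. These are the authors' values for each peak and served to describe, rank and filter peaks within a list. Positions are 1-based on GRCh38.

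Peaks were compared by overlap of at least 1 bp. Nuclear peaks were set against 1000 random placements on the same chromosome with their widths kept, which was the design fixed before the data were examined. Placement within 50000 bp of each peak's own position was added after the data were seen. Shares carry exact Clopper-Pearson intervals and counts carry exact Poisson intervals at 95% confidence. These cover counting error only, and amplified fragments are not independent molecules. With 1 library per group there was no replicate check, and no p-value between the libraries was computed. Ratios between the libraries in the closing observations, with their intervals and simulations, compare these libraries and not the conditions.

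Genes came from a RefSeq gene table of GRCh38.p14, with symbols, classes and extents. Strand, exons and a genome sequence were not used here. Several planned steps were therefore not run: base composition, sequence motifs, soft-masked repeats, placement matched on GC or outside assembly gaps, and classes for promoters, exons, introns and UTRs. In their place each summit was assigned to a protein-coding gene, another annotated gene, a gene-free interval or the rest of the intergenic sequence, in that order. A gene-free interval was a stretch of at least 1000000 bp with no annotated gene, a definition made after the data were seen. These 32 intervals covered 6.78% of the annotated span, which took the place of the sequenced length. Some genes near the starts of chromosomes 13, 14, 15, 21 and 22, and a few others, carry positions in the table that may count along a scaffold rather than the chromosome, so gene assignments there are uncertain.

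A gene had a peak if a summit lay within 1000 bp of its extent, since strand was not used to define upstream sequence. For 9 lists of 25 genes, fixed before the data were examined, the number of members with a peak was set against 10000 random lists of protein-coding genes matched on gene length in 20 bins. Genes were named by a rule fixed at the same time. It took the 8 highest peaks by −log10 q-value in protein-coding genes among shared, 0 Gy-only and 20 Gy-only peaks, and the 3 highest peaks of each class anywhere. It also took the 5 genes with the most peaks in each list, AIM2 itself and the members of the gene lists with a peak. Alternatives were stricter −log10 q-value limits of 3 and 5, a fold enrichment limit, merging within 10000 bp, other overlap definitions, equal list lengths, peak midpoints, protein-coding genes only and a wider gene window. Equal minimum peak lengths and longer gene-free intervals were added after the data were seen.

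Overlap and list counting were tested on simulated data. For the overlap step, 602 shared peaks were found where 600 had been planted among 1200 peaks set against 1929. For the list step, run on 20037 genes, all 10 planted members were found. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.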

Results

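DNA immunoprecipitated with an AIM2 antibody was sequenced from unirradiated HaCaT keratinocytes and HaCaT cells given 20 Gy of X-rays, with 1 library per group. The comparison addressed where the DNA recovered with this antibody lies with and without irradiation. No control library was used, so a peak can arise for reasons other than the antibody. The 0 Gy library held 10497630 fragments, of which the peak caller kept 8786091 after removing 16.3% as duplicates. The 20 Gy library held 7740043 fragments, of which 6423989 were kept and 17.0% removed, so its kept depth was 0.731 times that of the 0 Gy library. With no replicates, the values below describe these libraries, and no difference between them could be tested against replicate spread.

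Most peaks in both libraries lay in long stretches without annotated genes, and few lay in protein-coding genes. The 0 Gy list held 1936 peaks covering 524364 bp, with a mean width of 271 bp. The 20 Gy list held 1525 peaks covering 400726 bp, with a mean width of 263 bp. Per 1000000 kept fragments this was 220 peaks at 0 Gy and 237 at 20 Gy. These rates are not directly comparable, since 127 of the 20 Gy peaks were shorter than the 177 bp minimum of the 0 Gy call. With equal minimum lengths 1398 peaks were left at 20 Gy and all 1936 at 0 Gy. Of all called peaks, 1929 at 0 Gy and 1518 at 20 Gy were nuclear, and each list held 7 mitochondrial peaks.

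Gene-free intervals of at least 1000000 bp held 84.3% of nuclear summits at 0 Gy (95% interval 82.6 to 85.9, 1627 of 1929) and 82.5% at 20 Gy (80.5 to 84.4, 1253 of 1518). Random placement put 8.14% and 8.28% of summits there. Protein-coding genes held 41 summits at 0 Gy, or 2.13% (1.53 to 2.87), and 54 at 20 Gy, or 3.56% (2.68 to 4.62), where placement gave 42.0% and 42.1%. Other annotated genes held 2.95% and 3.16%, and the remaining intergenic sequence held 10.6% and 10.7%.

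Chromosomes 1, 5, 10 and 19, picked after the counts were seen, carried 888 of the 1929 nuclear peaks at 0 Gy (46.0%, 43.8 to 48.3) and 745 of the 1518 at 20 Gy (49.1%, 46.5 to 51.6), on 20.2% of the annotated span. Chromosome 19 held 227 peaks at 0 Gy (Poisson interval 198 to 259) and 175 at 20 Gy (150 to 203), which were 6.20 and 6.07 times the number expected from its span. Chromosome 6 held 6 and 4 peaks, against 107 and 84.0 expected. The expected numbers took span alone, and HaCaT cells are aneuploid, so peak density may also follow chromosome copy number, which was not analysed here. The 1 Mb window starting at 124 Mb of chromosome 1 had 100 peaks at 0 Gy and 84 at 20 Gy. The window at 26 Mb of chromosome 19 had 100 and 68, that at 40 Mb of chromosome 10 had 93 and 83, and that at 49 Mb of chromosome 5 had 88 and 81. The 10 fullest windows of each list held 39.5% and 41.1% of its nuclear peaks. On chromosome 19, 98.2% of the peaks at 0 Gy and 97.1% at 20 Gy lay in gene-free intervals. The repeat content of the crowded windows was not analysed here. With no input library, these counts cannot separate signal of the antibody from regions with more reads for other reasons.

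**Figure D1:**
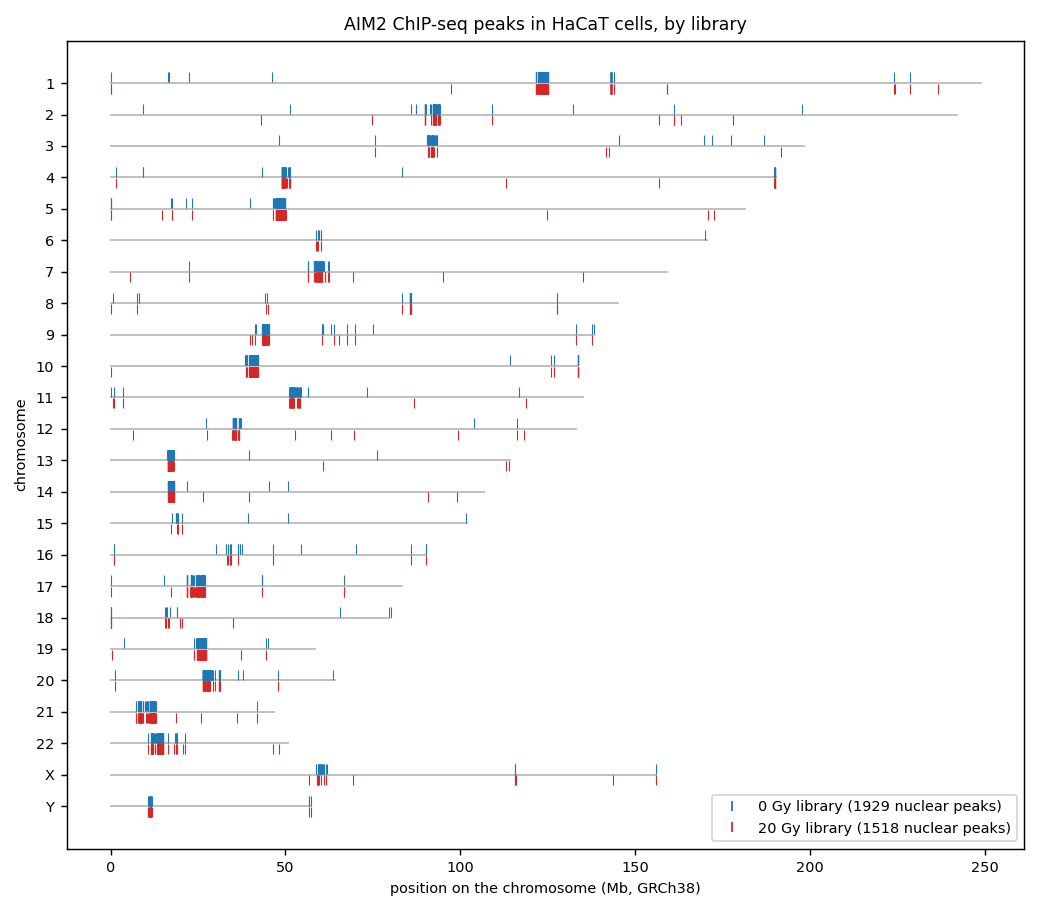
Position of every nuclear peak (x axis, Mb on GRCh38) along each chromosome (y axis), with ticks above the grey line for the 0 Gy library and below it for the 20 Gy library. Ticks of both libraries crowd into the same 1 or few blocks per chromosome, and chromosomes 1, 5, 10 and 19 hold 888 of 1929 and 745 of 1518 peaks.

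The libraries shared most of their strong peaks and few of their weak ones. At 0 Gy, 1054 of 1936 peaks overlapped a 20 Gy peak (54.4%, 52.2 to 56.7). At 20 Gy, 1057 of 1525 overlapped a 0 Gy peak (69.3%, 66.9 to 71.6). Of the nuclear peaks 1047 and 1050 were shared, where random placement on the same chromosome gave means of 1.09 and 1.10 and at most 5 and 6. Placement within 50000 bp of each peak, which keeps the crowded regions, gave means of 58.1 and 58.2 and at most 84 and 88. Among peaks with a −log10 q-value of at least 20, 396 of 404 were shared at 0 Gy (98.0%) and 295 of 301 at 20 Gy (98.0%). Below 3 the shares were 17.3% and 22.6%. Median pileups of shared and unshared peaks were 22 and 11 at 0 Gy, and 17 and 9 at 20 Gy. A peak found in 1 list only can have missed the caller's limit in the other.

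The 3 shared peaks with the highest −log10 q-values, ranked by the lower of the values in the libraries, lay outside protein-coding genes. The peak at chromosome 4, 49149171 to 49149840, had −log10 q-values of 2128 at 0 Gy and 1831 at 20 Gy, with pileups of 2310 and 1905. The peak at chromosome 3, 93470361 to 93470799, had −log10 q-values of 1656 and 1306, with pileups of 1462 and 1147. The peak at chromosome Y, 11721925 to 11722135, had −log10 q-values of 1451 and 1233, with pileups of 1293 and 1060. Some other shared peaks had higher pileups, up to 2515 at 0 Gy. Shared peaks in protein-coding genes included one assigned to both RANBP2, which encodes a nuclear pore protein, and SH3RF3, at chromosome 2, 109199330 to 109199848, with pileups of 90 and 75. MYC, which encodes a transcription factor of cell growth, carried 2 peaks in each library. DUX4, a homeobox gene of a subtelomeric repeat array, had a shared peak with pileups of 62 and 58. Pileups were 43 and 35 at ART1, an ADP-ribosyltransferase gene, and 53 and 27 at LMF1, a lipase maturation gene. They were 22 and 29 at DOCK1, 21 and 20 at PRKCA, which encodes protein kinase C alpha, and 16 and 12 at AP2A2, a clathrin adaptor gene.

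AIM2 itself had peaks in the 20 Gy library and none called in the 0 Gy library. The first, at chromosome 1, 159065946 to 159066264, had a pileup of 27 (Poisson interval 17.8 to 39.3), a fold enrichment of 14.4 and a −log10 q-value of 25.7. The second, at 159073261 to 159073499, had a pileup of 14 (7.65 to 23.5), a fold enrichment of 9.01 and a −log10 q-value of 10.6. The deeper of the libraries was the 0 Gy one. Whether the peaks lie in exons or introns was not analysed here.

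The 20 Gy-only peaks in protein-coding genes also included another DUX4 peak with a pileup of 27, itself shorter than the 177 bp minimum of the 0 Gy call, GAPDH with 12, FAM90A23 with 13, PHRF1 with 10 and ACTN2, a muscle alpha-actinin gene, with 10. LOC124904607 had a pileup of 11. LOC124905564, assigned to a peak at the start of chromosome 1 with a pileup of 12, is of uncertain position in the gene table. Anywhere in the genome, the 20 Gy-only peaks with the highest −log10 q-values were at chromosome Y, 11643651 to 11643822, chromosome Y, 11712526 to 11712698, and chromosome 22, 16359730 to 16359902. Their −log10 q-values were 318, 69.6 and 60.2, and their pileups were 255, 58 and 58, where the highest pileup of any unshared 20 Gy peak was 319. All 3 were shorter than the 177 bp minimum of the 0 Gy call, so no 0 Gy peak of that length could be reported.

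The 0 Gy-only peaks in protein-coding genes were led, by −log10 q-value, by ANKRD30BL, with a pileup of 29. Then came USP17L11 (13), FAM90A24 (19), FANK1 (12), GMEB2 (14), NBPF1 (17), FAM90A22 (15) and HPSE, which encodes heparanase (9). USP17L11, NBPF1 and the FAM90A genes belong to multicopy families, whose reads can be misplaced between copies. The ANKRD30BL peak also lies in the annotated pseudogenes LOC107985804 and LOC110467533. FANK1 also held a different peak at 20 Gy, with a pileup of 8. Among all 0 Gy-only peaks, those with the highest −log10 q-values were at chromosome 22, 16347186 to 16347364, chromosome 20, 31157399 to 31157915, and chromosome 1, 143187706 to 143187897. Their −log10 q-values were 158, 34.2 and 31.7, and their pileups were 147, 43 and 145, where the highest pileup of any unshared 0 Gy peak was 192.

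Of 20037 protein-coding genes, 44 had a peak at 0 Gy and 48 at 20 Gy, and 15 had one in both. In the 0 Gy list 3 genes had several peaks: DUX4, MYC and LMF1, each with 2, and the other 41 had 1. In the 20 Gy list DUX4 had 3, and AIM2, MYC, DOCK1, LMF1, PRKCA and RPSA2 had 2. At 20 Gy, 1 peak each of DUX4 and RPSA2 was shorter than the 177 bp minimum of the 0 Gy call, and the 2 DOCK1 peaks both overlapped the single 0 Gy one, so these counts are not directly comparable.

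The gene lists held few peaks. No p53 target, interferon-stimulated gene, keratinocyte gene or gene of other skin cell types had a peak in either library. Of the 25 inflammasome and cytosolic DNA sensing genes, AIM2 alone had peaks, at 20 Gy, and 3.31% of random lists had as many members with a peak. ATR, which encodes a DNA damage kinase, was the member of the DNA damage signalling and repair list with a peak at 20 Gy (pileup 8, 8.46% of random lists). DPYD was that of the common fragile site list (pileup 5, 25.4%). Neither of these lists had a member with a peak at 0 Gy, and neither the ATR nor the DPYD peak reached the 0 Gy minimum length. MYC was the only immediate early gene with peaks, at 0 Gy (2.89% of random lists) and 20 Gy (3.69%). Housekeeping genes with a peak were EEF2, a translation elongation factor gene, at 0 Gy (pileup 10, 3.19%), and ACTB (pileup 9) and GAPDH (pileup 12) at 20 Gy (0.02%). With 9 lists in each of the libraries, such percentages describe these libraries and are not tests. The counts rest on 1 or 2 genes each, and at a −log10 q-value of at least 3 EEF2, ACTB and DPYD were no longer called.

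The MYC peaks lay at chromosome 8, 127738244 to 127738992 and 127740440 to 127740958 at 0 Gy. Their pileups were 110 (90.4 to 133) and 80 (63.4 to 99.6). At 20 Gy the peaks spanned 127738244 to 127738978 and 127740425 to 127740958, with pileups of 180 (155 to 208) and 137 (115 to 162). These were higher in the library of lower depth, whereas 848 of the 1046 shared nuclear pairs had a lower pileup there (81.1%). The fold enrichments of the MYC peaks differed less, at 8.53 and 6.27 at 0 Gy and 9.81 and 7.48 at 20 Gy. Their local background came from the same library over windows of up to 10000 bp, which can hold both MYC peaks. Higher peaks can thus raise that background too, so fold enrichment can understate a rise.

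**Figure D2:**
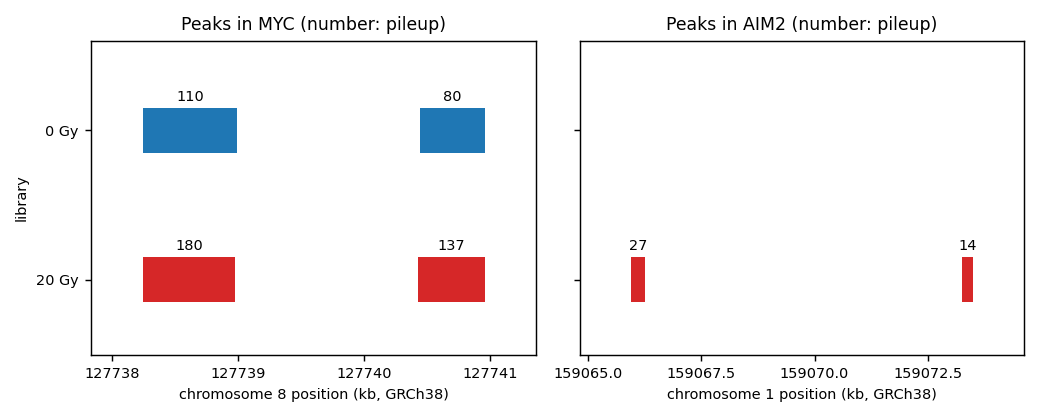
Peaks called in MYC (left) and AIM2 (right) in the 0 Gy and 20 Gy libraries (y axis) by position in kb on GRCh38 (x axis), with the pileup of each peak printed above its bar. MYC has 2 peaks in each library, with pileups of 110 and 80 at 0 Gy and of 180 and 137 at 20 Gy, and AIM2 has peaks of 27 and 14 at 20 Gy with none called at 0 Gy.

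The mitochondrial genome carried 7 peaks in each library, and all 7 overlapped. The strongest, at 2167 to 3970 at 0 Gy and 2167 to 3977 at 20 Gy, covers part of the ribosomal RNA gene RNR2 and ND1, and had pileups of 1100 and 1710. Over the 7 peaks pileups ran from 767 to 1100 at 0 Gy and from 1182 to 1710 at 20 Gy.

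**Figure D3:**
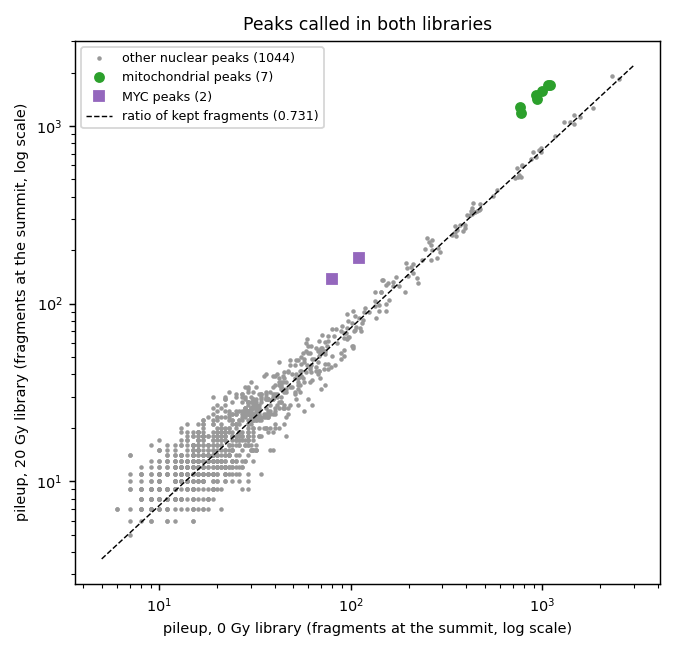
Pileup of each peak pair called in both libraries, 0 Gy on the x axis and 20 Gy on the y axis, both on log scales in fragments at the summit. The dashed line is the ratio of kept fragments, 0.731, around which most of the 1046 nuclear pairs lie, while the 7 mitochondrial and 2 MYC pairs lie above it.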

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

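All tests in this part were chosen after the results they measure had been seen. Mitochondrial DNA lay outside the comparisons with random placement, and its pileups relative to kept fragments were higher in the 20 Gy library than in the 0 Gy library. The strongest mitochondrial peak reached 266 fragments per 1000000 kept fragments at 20 Gy and 125 at 0 Gy. The median depth-scaled ratio of the 7 peaks was 2.16, above the 1.84 that bounds the middle 95% of 1046 nuclear pairs, which argues against a difference in sequencing depth. The highest of the 7 ratios was 1.09 times the lowest, within the 1.21 that counting error gives around a single ratio in 10000 simulations. Fold enrichment over the local background hardly differed, with a median over the 7 peaks of 2.854 at 0 Gy and 2.853 at 20 Gy. That background is itself mitochondrial signal of the same library, so a rise of the whole mitochondrial genome would largely cancel in the fold enrichment. One change in the amount of mitochondrial DNA would give a single ratio. So would any other change that raised all 7 peaks alike, so these values cannot single it out. With 1 library per group, an effect of irradiation and a difference between the library preparations cannot be told apart.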

How the results depend on the processing

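Alternatives were fixed before the data were examined, except equal minimum peak lengths, longer gene-free intervals and placement near each peak, which were added after. Of the values recomputed for the main comparisons, 57 stayed within their interval or within 1.5 times the main count and 51 moved. Some of the 57 could not move, since equal minimum lengths removed no peak from the 0 Gy list. No direction was tested, so a change of sign was not possible. Values are given for 0 Gy, then 20 Gy. With a fold enrichment at or above the list's median, peaks numbered 969 and 763 over 288958 and 217703 bp, 61.9% and 78.6% were shared, and 87.9% and 86.5% lay in gene-free intervals. Protein-coding genes then held 1.24% and 1.83%, any annotated gene 3.92% and 5.24%, chromosomes 1, 5, 10 and 19 held 55.2% and 56.2%, and the gene lists had 1 and 3 members with a peak. At a −log10 q-value of at least 5, 1010 peaks were left at 20 Gy, 58.7% and 80.7% were shared, protein-coding genes held 1.31% and 1.79%, any annotated gene 3.78% and 5.08%, the 4 chromosomes 51.9% and 54.5%, and the lists had 1 and 3 members. At a limit of 3, 56.8% and 73.6% were shared, or 58.9% and 75.8% against any peak of the other list; protein-coding genes held 2.33% at 20 Gy, any annotated gene 4.01% at 0 Gy, and the lists had 1 member at 0 Gy. These limits leave fewer peaks by construction. Merging peaks within 10000 bp left 1136 and 962 regions over 4241720 and 2991570 bp, with 57.6% shared at 0 Gy, 3.35% and 4.89% in protein-coding genes, 6.52% and 8.32% in any annotated gene, and 34.9% and 39.1% on the 4 chromosomes. Merging counts a crowded block once. Counting protein-coding genes only, in place of any annotated gene (5.08% and 6.72%), gave 2.13% and 3.56%. With equal numbers of top peaks 63.7% and 63.9% were shared, a near equality that follows from equal list lengths, since overlaps were nearly one to one. Reciprocal overlap of at least 50% gave 66.6% at 20 Gy, and equal minimum lengths, which removed 127 of the 20 Gy peaks, gave 72.5%. Except where named as a matter of construction, the cause was not tested. Alternatives listed beforehand that need a genome sequence, transcription starts or GC content were not run: soft-masked filtering, GC-matched placement, promoters of 3 kb, composition around the summit and matching on GC. The lowest called pileups were 6 at 0 Gy and 5 at 20 Gy, and no list was recomputed at a reduced depth. No paired analysis was possible because each group has 1 library.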

Other observations

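Several repeat-rich gene families, picked after their values were seen, carried peaks. DUX4 and its related copies held 20 peaks at 0 Gy and 16 at 20 Gy, of which 15 were shared in each list, with pileups of up to 283 and 180. The IGK immunoglobulin region held 7 and 6 peaks, with pileups of up to 251 and 235. Genes of the 45S ribosomal RNA array held 4 peaks in each library, with pileups of up to 72 and 54. The pseudogene ROCK1P1 held 3 and 4 peaks, the FAM230 family 5 in each, and the REXO1L family 3 in each. The FAM90A family held 2 peaks at 0 Gy and 1 at 20 Gy, none of them shared, and the USP17L family 1 at 0 Gy and 0 at 20 Gy. Reads of such families can be misplaced between copies.

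Relative to kept fragments, the MYC peaks were 2.24 times (exact interval 1.76 to 2.86) and 2.34 times (1.76 to 3.13) as high in the 20 Gy library, where the median of 1046 nuclear pairs was 1.06. Of the 1044 pairs other than MYC, 4 and 3 had ratios as high as these. Among the 245 of them with a pileup of at least 30 in both libraries none did, and the highest ratio was 1.64. Neither this comparison of ratios nor its limit of 30 was among those fixed before the data were examined. Fold enrichment of the MYC peaks over the local background differed less, at 8.53 and 6.27 at 0 Gy and 9.81 and 7.48 at 20 Gy. That background can include the MYC peaks themselves, so fold enrichment can understate a rise. Whether the MYC peaks lie in exons, as DNA copied from spliced transcripts would, was not analysed here. Among unshared nuclear peaks, protein-coding genes held 26 of 882 at 0 Gy (2.95%, 1.93 to 4.29) and 38 of 468 at 20 Gy (8.12%, 5.81 to 11.0). At a −log10 q-value of at least 3 the shares were 1.83% (0.978 to 3.11, 13 of 710) and 5.25% (3.09 to 8.27, 17 of 324). The counts in genes thus differed less than the shares. Of the 468 unshared 20 Gy peaks, 84 were shorter than the 177 bp minimum of the 0 Gy call, where no peak of that length could be reported. These shares were not recomputed at equal minimum lengths. Over all unshared peaks in protein-coding genes the median pileups were 8.5 at 0 Gy and 7 at 20 Gy, near the lowest called pileups of 6 and 5.

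The tests in the rest of this part were all chosen after the results had been seen. Beside GAPDH and ACTB, 20 Gy peaks lay in pseudogenes named after abundantly transcribed genes, such as RPS26P25, EEF1A1P5, RPL3P4 and PPIAP22. Of this class, EEF1A1P5 and EEF1A1P6 held a peak in both libraries. The RPS26P25 peak, with a pileup of 7, also lies in the protein-coding gene ANK2. Pseudogenes of ribosomal protein, elongation factor, FTH1, TPT1 and housekeeping genes held 9 peaks at 20 Gy and 4 at 0 Gy, where the highest of 1000 placements held 3 in each; without FTH1 and TPT1 the 0 Gy count was 3. The odds of a peak, relative to pseudogenes named after other protein-coding genes, were 11.3 times as high at 20 Gy (exact interval 2.34 to 108) and 2.51 times at 0 Gy (0.467 to 13.5), but relative to all other annotated pseudogenes, with the DUX4L and REXO1L copies among them, 2.85 times (1.14 to 6.55) and 0.935 times (0.238 to 2.69). Because this class was drawn up after such peaks had been seen, and exon positions were not used here, DNA copied from spliced transcripts and reads shared between similar gene copies cannot be told apart by these values.

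For peaks found in the 0 Gy list only, the lower depth of the 20 Gy library could not be separated from chance at the caller's limit. That lower depth would not by itself remove peaks from the deeper 0 Gy list, so the values below do not test it for 20 Gy-only peaks. The upper quartile of −log10 q-value of the unshared peaks lay below the median of the shared ones in both lists, at 7.28 against 14.1 at 0 Gy and 5.55 against 10.3 at 20 Gy, and 1.99% of the 20 Gy peaks with a value of at least 20 (0.735 to 4.29) lacked a partner. The shorter minimum length at 20 Gy covers all 3 of the 20 Gy-only peaks with the highest −log10 q-values, but only 4 of the 32 with a −log10 q-value of at least 10. At the 20 Gy rate per kept fragment the AIM2 peaks would have pileups of 36.9 (24.3 to 53.7) and 19.1 (10.5 to 32.1) at 0 Gy. These lie above the lowest pileups of 9 and 8 called there at a similar background, so peaks at that rate would have been high enough to call. The comparison is not a test of depth, because the 0 Gy library, which lacks the AIM2 peaks, was the deeper one. An effect of irradiation and a difference between the library preparations both stay open for AIM2, since each group has 1 library. DNA copied from spliced transcripts was not tested for AIM2, since exon positions were not used here.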
